A study of Homo sapiens with 2 samples.

How the data were processed

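Primary human airway epithelial cells, taken directly from airway tissue rather than from an established line, were the only cell type in the series. They were exposed for 18 h either to heat-killed Pseudomonas aeruginosa of the laboratory strain PAO1, at 100 bacteria per cell, or to phosphate-buffered saline (PBS). The array was a membrane spotted with DNA for target genes of NF-κB, the transcription factor family that drives many inflammatory genes. Per the labels' protocols, 500 ng of mRNA per sample was reverse transcribed into biotin-labelled cDNA with a mix of gene-specific primers and hybridised to 1 membrane. Bound biotin was developed with streptavidin-peroxidase and chemiluminescence on X-ray film, with an exposure of 1 min in the design text.

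Per the labels and design text, the authors measured each dot by densitometry, subtracted the background, and divided by the mean of the biotinylated DNA dots of the same membrane, so each deposited value is a ratio to those control dots. The software was GeneTools, whose version is not given in the sources used here. How the background was chosen, and whether the film was within its linear range, is not given there either. The control dots carry their own biotin. They therefore register the detection and film steps, but not the amount of labelled cDNA or its hybridisation.

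The deposited table held 285 dots, named by row (A to O) and column (1 to 19), with 1 value per membrane. The sources used here do not pair positions with genes, so no gene is named and none of the gene lists fixed beforehand could be applied. The 2 roles of a dot were taken from the values. The 33 dots of row O and column 19 averaged 0.992 on the PBS membrane and 1.00 on the PAO1 membrane, as the formula requires of the control dots, and were treated as such. The other 252 dots were treated as gene dots. Dots in columns 1 and 2, 3 and 4, and so on resembled each other far more than dots across the boundary of such pairs, so each odd and even neighbour was taken as 1 gene spotted in duplicate, which gave 126 pairs. On the PBS membrane the median difference was 0.0772 within a pair and 0.353 across a boundary. On the PAO1 membrane it was 0.0453 within a pair and 0.166 across a boundary.

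For each pair, the log2 ratio of PAO1 over PBS was computed per dot and averaged over the 2 dots. The SD over 2 dots that accompanies a value is technical, since both dots lie on the same membranes. A pair needed a value above 0 for both dots on both membranes, which left 104 pairs. A pair was called bright if its higher geometric mean of the 2 membranes was at or above the median of that quantity, 0.594. Counts used a limit of 2-fold either way. The series' own rule, a ratio over 1, was counted as well. With 1 sample per group no test between conditions is possible, no p-value is given, and the number of membranes limits the precision.

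The rule for naming, fixed before the data were examined, took the 12 highest and the 12 lowest ratios among bright pairs. Because positions are not paired with genes, only the extremes of those are named by position. The pairs H11/H12 and J11/J12 fall outside the rule and were chosen after their values were seen. The procedure was tested on simulated data made from the real PBS values. With the dot error of the bright pairs, all 20 of 20 pairs changed 4-fold were recovered and 0 of 32 unchanged pairs were called. With the larger dot error of all 104 pairs, 40 of 40 changed pairs were recovered and 2 of 64 unchanged pairs were called. That simulation gave every pair the same dot SD, 0.757. Pairs that were not bright (dim pairs) had a larger one, 1.04, so its false calls are too few for dim pairs. Changed pairs were simulated at 4-fold only, so recovery near the 2-fold limit was not tried. These simulations hold no error shared by a whole membrane or by a part of it.

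Alternatives were median centring, scaling to the total signal, a lowess fit on level with a span of 0.7, 2 filters on dim pairs, a pseudocount of 0.0592 (the 10th percentile of positive values), ratios of mean values, and limits of 1.5-fold and 3-fold. Scaling to constitutive genes was planned and not run, because no position is paired with such a gene. Further alternatives, chosen after seeing the data, used the control dots of one edge alone, trends over membrane position fitted to the control dots, single dots, blank cells taken as 0, and the table without rows F and G. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.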

Results

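The study asked which NF-κB target genes change in airway epithelial cells that meet killed P. aeruginosa. One membrane was hybridised with cDNA from PBS-treated cells and one with cDNA from cells exposed to PAO1, so every comparison rests on 1 sample per group. Gene dots ranged from 0.00133 to 1.98 times the control dots on the PBS membrane, with a median of 0.534 over the dots that had a value. They ranged from 0 to 1.41 on the PAO1 membrane, with a median of 0.321. The PBS membrane had 27 gene dots without a value and none listed at 0. The PAO1 membrane had no blank gene dots and 17 listed at 0.

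The control dots set the scale and were not uniform. Their coefficient of variation was 28.2% over 33 dots on the PBS membrane and 15.8% on the PAO1 membrane. The same control dot compared between membranes gave a log2 ratio of 0.05 ± 0.40 (mean ± SD, n = 33 dots), between -1.14 at A19 in the upper right corner and 0.69 at O17 near the lower right corner. Along the bottom edge, row O, the log2 ratio went from -0.58 at O1 to 0.69 at O17, a slope of 0.048 per column. For duplicate dots of bright pairs, the SD of the log2 ratios within a pair was 0.24, against 1.04 for dim pairs. These are SDs between neighbouring dots. The control SD of 0.40 is over dots along whole edges and includes the change with position, so it is not a like comparison.

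Gene pairs with strong signal were lower on the PAO1 membrane. None of the 52 bright pairs had a ratio over 1, both dots were below 1 in 51 of them, and 24 were at least 2-fold lower. Their median ratio was 0.544, a median log2 ratio of -0.88, and the SD between pairs was 0.45. The counts and the median of bright pairs depend on the scaling. Scaling to the total signal raised every log2 ratio by 0.74 and left 1 of all 104 pairs at least 2-fold lower. The 2 lowest bright pairs were G3/G4 and F5/F6, in the left part of the middle rows. G3/G4 measured 1.39 ± 0.08 on the PBS membrane and 0.422 ± 0.005 on the PAO1 membrane (mean ± SD, n = 2 dots), which is 3.29-fold lower. F5/F6 measured 1.40 ± 0.25 and 0.460 ± 0.012, which is 3.02-fold lower, with a log2 ratio of -1.59 ± 0.30 (SD, n = 2 dots). Both folds depend on the scaling: after the lowess fit on level the log2 ratios were -0.83 for G3/G4 and -0.70 for F5/F6, and after scaling to the total signal -0.98 and -0.85, all short of 2-fold. At the other end, D13/D14 measured 1.14 ± 0.003 and 1.08 ± 0.07, a log2 ratio of -0.07 ± 0.08 that is within its dot error, and its sign turned under several other scalings.

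**Figure D1:**
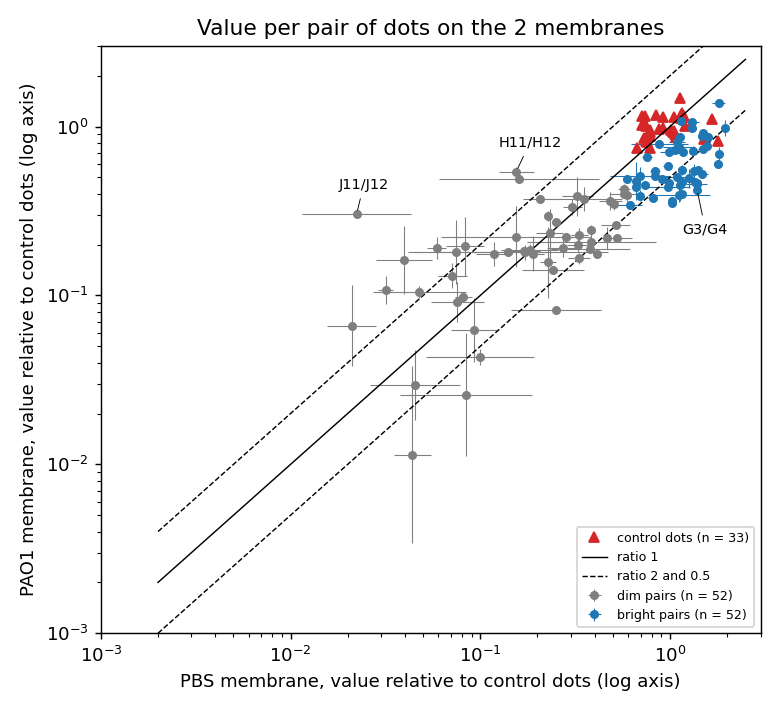
Value of each pair of dots on the PBS membrane (x axis) and the PAO1 membrane (y axis), relative to the control dots, both on log axes. Points are geometric means of 2 dots, thin bars run from the lower to the higher dot, and triangles are single control dots. All 52 bright pairs lie below the line of ratio 1, while the 33 control dots lie on both sides of it.

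Over all 104 pairs measured on both membranes, 32 were at least 2-fold lower and 10 at least 2-fold higher with PAO1. By the series' own rule of a ratio over 1, 26 pairs were higher and 78 were not. The median ratio was 0.663 and the median log2 ratio -0.59. Both dots passed the 2-fold limit in 20 of the 32 lower pairs and in 7 of the 10 higher pairs. These counts depend on the scaling: relative to the median pair, 14 pairs were at least 2-fold higher and 4 at least 2-fold lower, and after scaling to the total signal the numbers were 18 and 1. After a lowess fit on level was subtracted they were 6 and 6. Across all pairs, which are not independent replicates, values on both membranes had a Spearman correlation of 0.85. Over narrower ranges of signal it was lower, with 0.48 among the 52 bright pairs and 0.60 among the 52 dim pairs.

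The ratio changed with the strength of the signal. In the upper tertile of level, the median log2 ratio was -0.88, and 0 of 35 pairs had a ratio over 1. In the middle tertile it was -0.63, and 6 of 34 pairs had a ratio over 1. In the lower tertile it was 0.06, with 20 of 35 pairs over 1, and the SD between duplicate dots was 1.16 there.

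All 10 pairs that were at least 2-fold higher with PAO1 were dim, with a median of 0.0532 on the PBS membrane and 0.186 on the PAO1 membrane. H11/H12, near the centre of the membrane, reached the highest PAO1 level among them. It measured 0.158 ± 0.046 with PBS and 0.541 ± 0.051 with PAO1 (mean ± SD, n = 2 dots), a ratio of 3.49 and a log2 ratio of 1.80 ± 0.29. J11/J12 had the highest ratio, with 0.0273 ± 0.0223 and 0.304 ± 0.008 and a log2 ratio of 3.77 ± 1.38. Its PBS value is close to background, and with a pseudocount of 0.0592 its log2 ratio was 2.09. Both pairs stayed at least 2-fold higher under every alternative that included them.

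The lower pairs were grouped on the membrane. All 10 pairs of rows F and G in columns 1 to 10 were at least 2-fold lower, with ratios between 0.304 and 0.397 and a mean log2 ratio of -1.50 ± 0.12 (SD, n = 10 pairs). This block was picked after its values were seen. It held 8 of the 12 lowest bright pairs, and the rest lay outside it. The membrane was also split after column 10, a cut that was not planned beforehand. Among bright pairs, 22 of 29 in columns 1 to 10 were at least 2-fold lower, against 2 of 23 in columns 11 to 18. The median log2 ratio was -1.29 on the left and -0.48 on the right. Of the 12 lowest bright pairs, 11 lay in columns 1 to 10, and all 12 of the highest lay in columns 11 to 18. The control dots of row O had a gradient in the same direction. With a linear plane over row and column, fitted to the log2 ratios of all control dots, subtracted (a correction chosen after seeing the data), 3 of 52 bright pairs were at least 2-fold lower and 17 had a ratio over 1. That plane rested in part on A19 and B19: fitted without them, it gave 10 bright pairs at least 2-fold lower and 8 over 1.

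**Figure D2:**
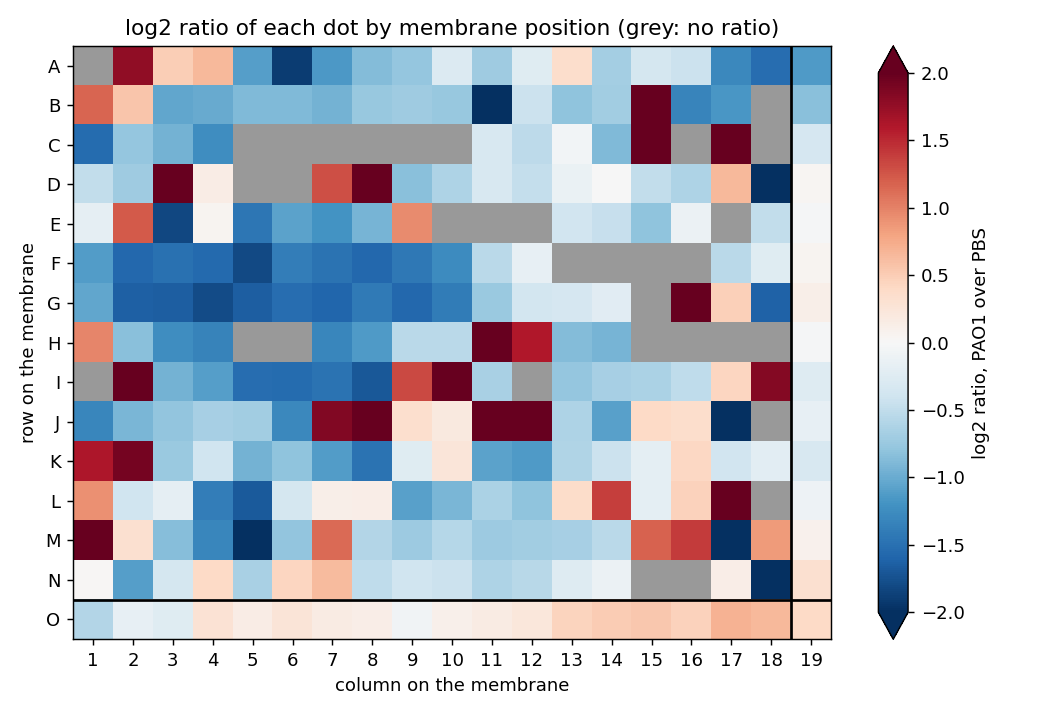
The log2 ratio of PAO1 over PBS for each dot, drawn at its row (A to O) and column (1 to 19) on the membrane, with blue lower and red higher with PAO1, colours saturated beyond 2 either way, and grey where a value was blank or 0. Black lines set off the control dots of row O and column 19, and the block of rows F and G in columns 1 to 10 is uniformly lower.

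**Figure D3:**
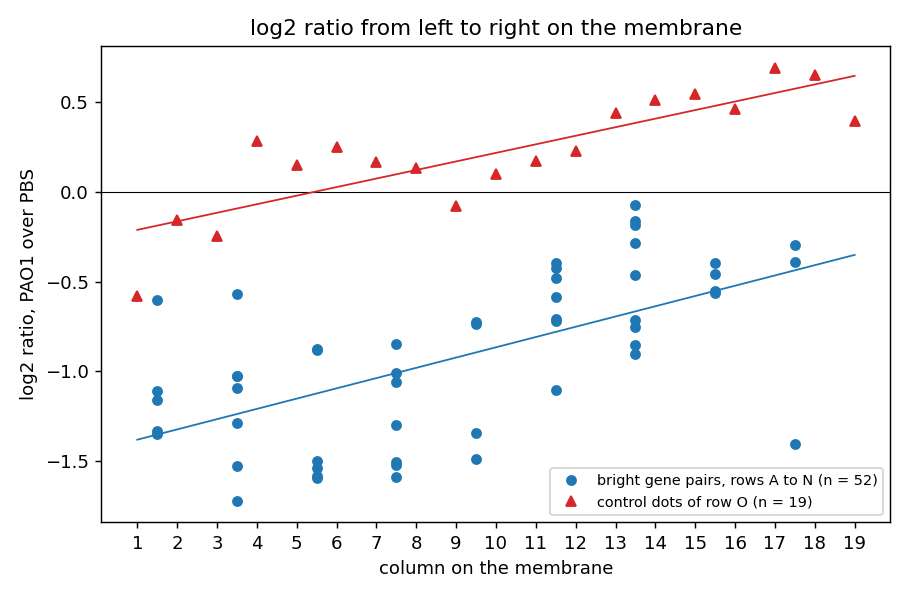
The log2 ratio of PAO1 over PBS (y axis) against the column on the membrane (x axis) for 52 bright gene pairs (circles) and 19 control dots of row O (triangles), with a least-squares line for each. Both sets rise from left to right, and the gene pairs lie below the control dots over most of the width.

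Of the 126 pairs, 22 had no ratio because a dot was blank or listed at 0. None of these was bright on either membrane. Blank PBS cells may stand for values that the PAO1 column lists as 0; the sources used here do not say. With blanks taken as 0 and the pseudocount added, 39 of 126 pairs had a ratio over 1, 11 were at least 2-fold higher and 23 at least 2-fold lower. Both PBS dots were blank in 9 pairs and 1 of them in another 9. At the 27 dots blank on the PBS membrane, 11 were listed at 0 on the PAO1 membrane and 16 had a value above 0, with a median of 0.0291 over all 27. The other 6 dots listed at 0 with PAO1 had PBS values of up to 0.175.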

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

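The dots without a PBS value take no part in the comparisons, and some had signal with PAO1. The highest was G15, at 0.415 times the control dots. Its duplicate G16 measured 0.268 on the PAO1 membrane and 0.0404 on the PBS membrane. What a blank cell stands for is not given in the sources used here, so no fold is given. No group held enough samples to look for a sample apart from the others, and no contrast was measured in more than 1 setting.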

How the results depend on the processing

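The direction of the whole array depends on the scaling. Lowess and the total signal move it in part by construction. The lowess curve is fitted to these same ratios, so their median lands near 0. Total-signal scaling makes the summed gene signals of both membranes equal, so it offsets a drop that bright dots carry. The median log2 ratio of -0.59 became -0.015 after the lowess fit, -0.094 after the control dot plane, and reversed to 0.14 after scaling to the total signal, and it kept its sign in the other alternatives except median centring, which sets it to 0. The 10 pairs at least 2-fold higher became 18 with the total signal, 6 with lowess, 0 among bright pairs, 2 with both values at or above the 25th percentile, and 5 with the pseudocount. The 32 pairs at least 2-fold lower became 4 with median centring, 1 with the total signal, 6 with lowess, 53 with the 1.5-fold limit, 6 with the 3-fold limit, 6 with the plane, and 13 with the plane fitted without A19 and B19. The 26 pairs with a ratio over 1 became 52 with centring (by construction) and 51 with lowess (near that by construction). They became 62 with the total signal, 0 among bright pairs, 13 with the percentile filter, and 47 with the plane. Over 219 single dots, 28 were at least 2-fold higher, 63 lower and 57 over 1. Beyond what holds by construction, the cause of these changes was not tested. Scaling to row O or to column 19 alone kept all these results within 1.5 times. G3/G4 and F5/F6 stayed lower in every alternative that included them as pairs, with log2 ratios of -0.83 and -0.70 after lowess as the smallest changes; both also fell short of 2-fold with the total signal (-0.98 and -0.85) and the plane (-0.99 and -0.85), and F5/F6 with median centring (-0.998). D13/D14 lay between -0.46 and 0.81. H11/H12 lay between 1.48 and 2.54, and J11/J12 between 2.09 and 4.51. The numbers given to the samples pair nothing, since each group has 1 sample.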

Other observations

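All tests in this part were chosen after the results were seen, and each describes these 2 membranes only. F17/F18 was the brightest pair on the PAO1 membrane, at 1.38 ± 0.04, and ranked 3 of 104 on the PBS membrane, at 1.81 ± 0.20 (SD, n = 2 dots). Gene dots above the mean of the control dots numbered 71 with PBS and 8 with PAO1. Of the gene dots, 5 with PBS and 0 with PAO1 exceeded every control dot of their membrane.

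The lower values of bright pairs with PAO1 go against what a panel of NF-κB targets would show if bacteria raised most of them. Scaling to either edge of control dots alone leaves the bright pairs lower, with a median log2 ratio of -0.73 for column 19. Which edge sets the scale therefore does not account for the lower values. These 2 scalings move every log2 ratio by only -0.20 (row O) or 0.15 (column 19), so they do not test other uses of the control dots. Scaling to the total signal, which does not use the control dots, raised every log2 ratio by 0.74, against a bright median of -0.88. That scaling makes the summed gene signals of both membranes equal, so by construction it offsets a drop that bright dots carry. A single factor for the whole membrane, such as less labelled cDNA, would move every pair alike if the film response were linear and dots lay well above background. The linear range of the film is not given, and the median log2 ratio was -0.88 in the upper tertile of level but 0.06 in the lower. Under those conditions such a factor cannot alone give a slope over columns. That slope stayed at 0.048 or more per column with each column pair left out. The slope does not tell whether such a factor set the low level of the bright pairs. Such a factor together with uneven detection stays open. About a plane over position, bright pairs spread 2.15 times as widely as duplicate dots allow but 1.41 times as widely as the control dots. The bright SD is of means of 2 dots and the control SD of single dots, so 1.41 may be too low for a like comparison. The control dots also do not register the yield of labelled cDNA. Uneven detection cannot be told apart from an effect of the bacteria. The plane over the control dots moved the bright median from -0.88 to -0.42, or to -0.57 when fitted without A19 and B19. That plane is extrapolated from 2 edges. Its slope down the rows (0.084 per row, or 0.062 without A19 and B19) was not seen in bright pairs (-0.005). Fitted down column 19 alone, the control dots had 0.063 per row, and 0.026 without A19 and B19. Without those 2 dots, the plane's row slope thus rests in part on the level of row O. A fall in these transcripts after PAO1 stays open and untested.

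The rise of the ratio from left to right may be a detection gradient, which is a hypothesis. Bright pairs had a slope of 0.057 per column in a fit with row and column, between 0.048 and 0.069 with each column pair left out, and 0.043 without rows F and G. Row O had 0.048, between 0.040 and 0.053 with each dot left out. These ranges overlap, but they show the weight of single points and not the precision of a slope. The overlap therefore does not decide whether gene and control dots share 1 gradient. With the slope of row O subtracted and the level of the membrane kept, 16 of 52 bright pairs were at least 2-fold lower in place of 24. Their median log2 ratio was then -0.79, and 0 had a ratio over 1. With the fitted line of row O subtracted, which also sets the level by row O, 27 were at least 2-fold lower and the median was -1.005. Dim pairs, with a dot SD of 1.04, had a slope of -0.017, so they did not show the rise that a gradient over all dots would give. A layout of the array that groups genes by behaviour was not tested, because positions are not paired with genes.

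Dots weak on the PBS membrane were mostly higher with PAO1, but picking dots for a low PBS value by itself favours this. The limit used, 0.160, was the highest PBS value among the 10 pairs at least 2-fold higher. Classes that use both membranes showed little of it. Of the dim pairs, 26 of 52 had a ratio over 1, with a median log2 ratio of -0.05. In the lower tertile of level it was 20 of 35 pairs, with a median of 0.06. Of the 54 gene dots with PBS values above 0 and up to 0.160, 41 had a higher value with PAO1, 13 did not, and 5 of these were listed at 0. The median of PAO1 minus PBS was 0.0569 over these dots, and 0.117 over the 10 pairs that were at least 2-fold higher, which were selected for a large value. H11/H12 differed by 0.385. D3/D4 rested on D3, with log2 ratios of 3.08 at D3 and 0.14 at D4.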
